A study of Mus musculus with 4 samples.

How the data were processed

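Single-cell transcriptomes were measured in mouse ear skin from 2 preparations: all skin cells, called whole skin here, and the cells left after magnetic removal of CD326-bearing cells, called CD326-negative skin. CD326 is the protein product of Epcam, an adhesion molecule of epithelia. Per the labels, both preparations held mice with and without Abhd12b, some given repeated hypochlorite injections as a model of scleroderma (200 µl into the back on 5 days a week and 20 µl into an ear 2 times a week, for 6 weeks) and some not. Each preparation was deposited as 1 cDNA library, in which all these mice were pooled, and 1 hashtag library, which counts barcoded antibodies against CD45 or against class I MHC molecules that mark the origin of a cell. Which hashtag carried which mouse, genotype or treatment is not given in the sources used here, so neither genotype nor treatment was compared, and hashtags carry no condition here. Values per hashtag are given as values, ranges and medians, as the number of equally named hashtags that differed in the same direction, and in a correlation between the libraries.

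Cells were captured on a BD Rhapsody device and amplified by TAS-Seq, a terminator-assisted method for whole transcriptomes, per the labels' protocols. GRCm38 is the genome build, and Seurat 4.0.4 with R 4.1.3, and R 4.2.1, are the tools, that the submitters' processing notes name; the aligner and the counting tool are not given in the sources used here. The deposited cDNA files hold counts, whole numbers per gene and cell barcode, not normalised by the authors. Per the file headers each barcode carries the authors' own hashtag call, 1 of 12 hashtags or doublet. The deposited hashtag files hold counts per barcode for each of the 12 hashtags, over barcodes with and without a cell. Whether molecular identifiers were collapsed is not stated, and the sizes of the counts did not settle it, so a count may be a read and not a molecule. All intervals cover counting error only. Gene positions were taken from the RefSeq table of assembly GRCm38.p6 by gene symbol, and are the whole extent of a gene with its introns.

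The whole skin file held 15438 barcodes, 30993 genes and 607898247 counts, with a median of 28549 counts and 3050 detected genes per barcode. The CD326-negative file held 16895 barcodes, 32411 genes and 774812915 counts, with a median of 33320 counts and 3200 detected genes. A barcode was kept with 500 or more detected genes, at most 25% of counts on mitochondrial genes, 10 or more hashtag counts and 75% or more of these on 1 hashtag. The mitochondrial limit alone met 490 barcodes of whole skin and 488 of CD326-negative skin. The hashtag rule left out most of the rest and did not treat cell classes alike, since classes with weak hashtag labelling were left out more often; shares are therefore also given with only the barcodes that the authors called doublets left out. The rules left 8689 cells of whole skin and 8028 of CD326-negative skin, or 14465 and 15836 by the authors' call. No doublet caller beyond the hashtags was relied on: Scrublet, as built into scanpy, marked 4 cells of whole skin (0.0460%) and 7 of CD326-negative skin (0.0872%), too few for it to have worked.

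Counts were scaled to 10000 per cell and log-transformed, and both libraries were clustered together with scanpy 1.11.5 on 2000 variable genes, 30 principal components and 15 neighbours, without integration (Leiden resolution 1, igraph 0.11.9, leidenalg 0.10.2), giving 35 clusters. Clusters were named "X-like" from markers of 24 classes fixed before the data were examined. The rule that scores a cluster against these markers was revised after the data were examined: a cluster took the class with the most markers among its top 10 genes by fold over all other cells. Ties went to the class with more markers detected in 10% or more of the cluster's cells at a log2 excess of 1 or more, and then to the higher mean excess. Clusters with under 3 such markers, or in which a class of another lineage had the highest mean excess, stayed unnamed. This gave 19 classes; 4 clusters stayed unnamed and held 2.66% of whole skin and 2.94% of CD326-negative cells. Among the named clusters, 1 fibroblast-like cluster of 51 cells was led by the heat shock genes Hspa1b, Hsph1 and Hspa1a. Proliferation genes such as Mki67 and Top2a led 1 T cell-like, 1 basal keratinocyte-like and 1 mast cell-like cluster.

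Each preparation is 1 library, so no test between them was possible, no p-value or standard error is given, and differences have no replicate check. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals. Gene levels are counts summed over cells, as counts scaled to a common total (CPM) with exact Poisson 95% intervals, and differences are log2(CPM + 1) in whole skin minus log2(CPM + 1) in CD326-negative skin. A gene was called where this was 1 or more in size, that is 2-fold, the intervals did not overlap and the larger sum held 50 or more counts; this is a rule of size between 2 libraries. Level differences of low genes are understated on this scale. Within a class the same was done where each library held 200 or more of its cells, which 8 classes met. The median difference of each of 14 gene lists fixed beforehand, over members with 10 or more counts, was ranked among those of 10000 random lists of the same size matched on expression. For list genes the class of highest CPM was found among classes of 100 or more cells, with 10 or more counts there. Shares of cells with a count were also taken after each cell was thinned to 10000 counts, and thinned values are those to compare between depths. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3 for TMM factors alone.

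Named genes followed a rule fixed beforehand: the 10 largest differences in each direction among called genes of 50 CPM or more in the higher library, leaving out mitochondrial, ribosomal, unannotated genes and pseudogenes. The rule also took the 4 largest of each list among those with 50 or more counts, the 5 largest in each direction within a class, Epcam and Abhd12b, and the genes of both lipid lists. The level of 1 list gene is not reported here; the counts and medians of its list include it. Of the list genes 1 was not found in the files, as was 1 marker. On simulated counts for the 33056 genes of both libraries, all 50 genes changed by 3 on the log2 scale and 79 of 100 changed by 1.5 were called, as were all 47 of these with 10 CPM or more. None of 32856 unchanged genes and none of 50 changed by 0.5 was called. On simulated fibroblast-like sums all 100 genes changed by 1.5 and all 50 changed by 3 were called, and none of 32856 unchanged genes. The simulated sums were Poisson counts around 1 pooled mean per gene, without variation between cells or hashtags. They check that the rule works as written and do not give its error on the real libraries.

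Alternatives set beforehand were other limits on detected genes and mitochondrial counts, barcodes of several hashtags kept, other clustering resolutions, each library clustered alone, cells weighted equally, other pseudocounts, TMM factors, other count minimums, other hashtag limits and each hashtag left out in turn. Chosen after the data were examined were the authors' doublet call in place of the 75% rule (also clustered afresh), a requirement that 10 or more of the 12 hashtags go in the same direction, and the cell with the highest count of each gene left out.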

Results

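Single-cell RNA sequencing was carried out on ear skin of mice with and without Abhd12b, with and without the hypochlorite model of scleroderma, in which repeated injections of an oxidant bring on thickening of the skin. The cells of all mice were pooled into 1 cDNA library of whole skin and 1 of CD326-negative skin, each with its own hashtag library. After filtering, whole skin held 8689 cells with 375834958 counts (median 32217 counts and 3253 genes per cell) and CD326-negative skin 8028 cells with 387533497 counts (median 35483 counts and 3309.5 genes). The labels give each preparation 1 library and name no genotype or treatment for a hashtag, so the comparison open to these data is that of whole with CD326-negative skin: which cells and transcripts the removal of CD326-bearing cells took away, and which it left enriched. There are no replicate libraries, so each difference is between 2 libraries. How many hashtags went in the same direction is given as a description.

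Abhd12b, a gene of the alpha/beta-hydrolase family and the gene deleted in part of the mice, was mainly a transcript of the upper epidermis in these libraries. In whole skin it stood at 15.04 CPM (95% interval 14.6 to 15.4) and in CD326-negative skin at 1.38 CPM (1.27 to 1.51), a log2 difference of 2.75 (2.62 to 2.88), and it was higher in whole skin in all 12 hashtags. Suprabasal keratinocyte-like cells, the differentiating layers of the epidermis, held the most in both libraries, 56.2 CPM in whole skin and 49.7 CPM in CD326-negative skin. Basal keratinocyte-like cells held 13.95 and 16.7 CPM, and hair follicle keratinocyte-like cells of whole skin 9.95 CPM. Taking all keratinocyte-like cells together, the level was 34.2 CPM (33.2 to 35.1) in whole skin and 30.7 CPM (27.8 to 33.8) in CD326-negative skin, while the share of such cells was 9.86 times higher in whole skin. At 10000 counts per cell, an Abhd12b count was seen in 24.0% of suprabasal keratinocyte-like cells of whole skin (37.1% unthinned) against 0.591% of fibroblast-like cells (2.51% unthinned), at median depths of 49498 and 54094 counts. Since each library pools both genotypes, and the deleted part of the gene (chromosome 12, 70154124 to 70190096, GRCm38) is not given in the sources used here, these values check no label.

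Removal of CD326-bearing cells took out most of the epithelium of the skin and left the connective tissue, the vessels and most, but not all, classes of leukocytes. Keratinocyte-like cells of all kinds were 38.6% of whole skin (37.5 to 39.6) and 3.91% of CD326-negative skin (3.498 to 4.36), 9.86 times lower. Hair follicle keratinocyte-like cells were 6.95% (6.43 to 7.51) and 0.0249% (0.00302 to 0.0900), which was 2 cells. The 75% hashtag rule kept only these 2 of 31 such barcodes of CD326-negative skin, and by the authors' doublet call the class was 11.3% and 0.183%. Sebocyte-like cells, the lipid-secreting cells of the sebaceous gland, were 1.21% of whole skin, and Langerhans cell-like cells, the antigen-presenting cells of the epidermis, were 0.633%. Of either class 0 of 8028 CD326-negative cells were found, which allows a share of up to 0.0374% by a limit of 3 counts (exact binomial upper bound 0.0459%). Basal keratinocyte-like cells made up 16.7% and 2.62%, and suprabasal keratinocyte-like cells 14.9% and 1.27%. All of these classes were higher in whole skin in each of the 12 hashtags.

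Vascular endothelial-like cells made up 3.14% of whole skin (2.79 to 3.53) and 7.67% of CD326-negative skin (7.10 to 8.28), and mast cell-like cells 4.06% (3.66 to 4.50) and 9.08% (8.46 to 9.73). The collagen-producing fibroblast-like cells were 11.9% (11.3 to 12.6) and 24.5% (23.5 to 25.4). Pericyte or smooth muscle-like cells were 2.07% and 3.94%. These 4 classes were higher in CD326-negative skin in all 12 hashtags. T cell-like cells were 11.8% and 17.1% and chondrocyte-like cells, of the ear cartilage, 1.62% and 2.34%, each higher in CD326-negative skin in 11 of 12 hashtags. Neutrophil-like cells were 3.18% and 4.83%, dendritic cell-like cells 3.13% and 4.43%, basophil-like cells 0.483% and 1.11%, higher in CD326-negative skin in 7, 9 and 6 hashtags and lower in 2, 3 and 2. Schwann-like cells, which ensheath nerves, were 1.37% and 1.64%, innate lymphoid or NK-like cells 0.633% and 0.872%, lymphatic endothelial-like cells 0.760% and 0.859%, and melanocyte-like cells 0.311% and 0.324%, each with overlapping intervals. By the authors' doublet call the intervals lay apart for Schwann-like (1.96% and 2.93%), lymphatic endothelial-like (1.94% and 2.51%) and melanocyte-like cells (0.484% and 0.796%), but overlapped for dendritic cell-like cells, at 1.92% (1.70 to 2.16) and 2.34% (2.11 to 2.59). Unnamed clusters held 2.66% and 2.94%, and 2.59% and 3.76% by that call.

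The 75% hashtag rule kept leukocytes and connective tissue cells unequally, and the shares move with it. In whole skin it kept 98.6% of T cell-like barcodes, which carried a median of 13424 hashtag counts, but 39.6% of fibroblast-like barcodes, which carried a median of 216, and 17.2% of chondrocyte-like barcodes. With the authors' doublet call in its place, fibroblast-like cells were 17.4% and 31.4%, vascular endothelial-like cells 7.06% and 14.02%, mast cell-like cells 2.55% and 4.73%, T cell-like cells 7.16% and 8.76%, and keratinocyte-like cells together 35.9% and 3.14%. Chondrocyte-like cells were 5.06% and 7.51%, pericyte or smooth muscle-like cells 3.44% and 6.74%, neutrophil-like cells 1.96% and 2.56%, and basophil-like cells 0.297% and 0.5999%. Macrophage or monocyte-like cells did not keep their difference. They were 12.5% (11.8 to 13.2) and 14.5% (13.7 to 15.3) under the 75% rule, higher in CD326-negative skin in 7 of 12 hashtags. Under the authors' call they were 7.96% (7.53 to 8.42) and 7.72% (7.31 to 8.15). Their share ranged from 3.30% to 21.1% over the hashtags of whole skin under the 75% rule. A hashtag held 567 to 877 cells of whole and 319 to 1069 of CD326-negative skin, so the pooled shares also depend on the mix of hashtags.

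Epcam (chromosome 17, 87635979 to 87651127, GRCm38), which encodes CD326, was 99.3 CPM (98.3 to 100.4) in whole skin and 7.22 CPM (6.95 to 7.49) in CD326-negative skin, a log2 difference of 3.61 (3.55 to 3.67), in the same direction in all 12 hashtags. Langerhans cell-like cells carried the most in whole skin, 930.2 CPM, followed by hair follicle keratinocyte-like cells at 523 CPM, suprabasal keratinocyte-like cells at 152 CPM, basal keratinocyte-like cells at 120.2 CPM and sebocyte-like cells at 92.6 CPM. Epcam was among the fixed markers of the Langerhans cell class, so its level there is not independent of the name. The top 10 genes of that cluster held 3 of these markers, Cd207, H2-M2 and Ltc4s, and not Epcam. The keratinocyte-like cells that remained in CD326-negative skin held less Epcam, 59.2 CPM in basal and 39.1 CPM in suprabasal ones. As 1 group they held 50.3 CPM (46.6 to 54.1) against 201 CPM (199 to 204) in whole skin, a gap to which the loss of hair follicle keratinocyte-like cells adds. Outside the epithelium the level was also lower in CD326-negative skin: 19.9 and 7.73 CPM in fibroblast-like cells, 34.7 and 19.1 CPM in T cell-like cells, 33.5 and 4.66 CPM in dendritic cell-like cells, and 5.34 and 0.199 CPM in mast cell-like cells. At 10000 counts per cell an Epcam count was found in 23.7% of whole skin cells and 3.42% of CD326-negative cells (29.5% and 5.95% unthinned), leaving out 855 and 545 shallower cells. In mast cell-like cells of whole skin, which should lack the gene, the thinned share was 1.502% (5.10% unthinned), at a median of 26131 counts against 32217 over all cells. Most other classes outside the epithelium had a higher thinned share there. It was 3.10% in macrophage or monocyte-like, 4.23% in vascular endothelial-like, 9.36% in T cell-like and 9.94% in fibroblast-like cells.

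**Figure D1:**
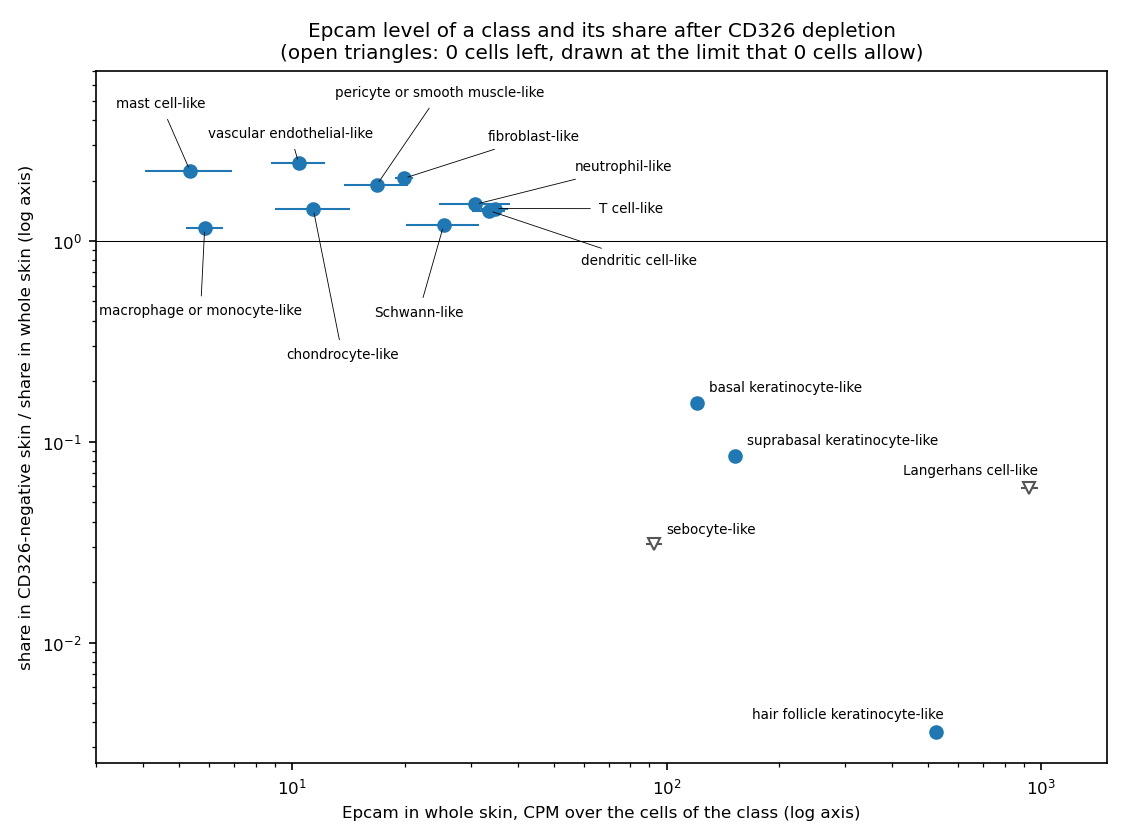
Epcam level of classes of 50 or more cells in whole skin (CPM, log axis), against the ratio of their shares. Innate lymphoid or NK-like and lymphatic endothelial-like cells are not drawn. Horizontal bars are exact Poisson 95% intervals. Epcam was among the markers used to name Langerhans cell-like cells. The ratio is the share of a class in CD326-negative skin over its share in whole skin (log axis, no interval drawn). The open triangles are sebocyte-like and Langerhans cell-like cells, of which 0 were left, drawn at the limit that 0 cells allow; classes with 92.6 CPM or more of Epcam lie below the line of equal shares.

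Over all cells the transcripts that stood highest in whole skin belonged to hair follicle, sebaceous gland and upper epidermis, and those that stood highest in CD326-negative skin to vessels, pericytes, cartilage and fibroblasts. By the size rule 949 genes were at least 2-fold higher in whole skin and 689 in CD326-negative skin, out of 33056 genes, of which 24202 had 50 or more counts in a library. The largest differences were those of Defb6, a beta-defensin (chromosome 8, 19225478 to 19228209), with 195 and 0.108 CPM (log2 7.47), Cst6, a cysteine protease inhibitor (chromosome 19, 5344705 to 5349574), with 566 and 3.44 CPM (6.995), and the keratin gene Krt79 with 218 and 1.01 CPM (6.77). With the keratin Krt17 (log2 5.85) these were highest in hair follicle keratinocyte-like cells. Fa2h, the fatty acid 2-hydroxylase, stood at 159 and 1.51 CPM (5.99) and was highest in sebocyte-like cells, as were Sdr16c6 (5.21), which encodes a retinol dehydrogenase, and Psapl1 (4.75). The keratin Krt77 (5.55) and the cornified envelope precursors Sprr1b (5.14) and Sprr1a (4.79) were highest in suprabasal keratinocyte-like cells. These 10 genes were higher in whole skin in all 12 hashtags.

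Among the genes higher in CD326-negative skin, Selp, the P-selectin of activated endothelium (chromosome 1, 164115264 to 164150026), stood at 143 and 382 CPM (log2 -1.42). Lrg1 stood at 38.9 and 112 CPM (-1.51), Iigp1, an interferon-inducible GTPase, at 43.7 and 118 CPM (-1.42) and Tmem252 at 22.7 and 67.9 CPM (-1.54). All 4 were highest in vascular endothelial-like cells. Tagln, a smooth muscle actin-binding protein, stood at 31.0 and 85.9 CPM (-1.44), and Dlk1, a Notch-related protein of progenitor cells, at 23.7 and 64.6 CPM (-1.41); both were highest in pericyte or smooth muscle-like cells. H19, an imprinted non-coding RNA (17.9 and 53.0 CPM, -1.51), and Angptl7 (35.5 and 98.8 CPM, -1.45) were highest in chondrocyte-like cells. Cxcl9, a chemokine that interferon-gamma induces (22.8 and 74.7 CPM, -1.67), and Reg3g, an antimicrobial lectin (30.2 and 80.1 CPM, -1.38), were highest in fibroblast-like cells. Tmem252, Lrg1, Tagln, Iigp1 and Selp were higher in CD326-negative skin in all 12 hashtags, Cxcl9 and Dlk1 in 11, Angptl7 and Reg3g in 10 and H19 in 8. A single cell held 20.9% of the Cxcl9 counts of CD326-negative skin, and Reg3g stood at -0.99 when cells were weighted equally.

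The number of genes higher in CD326-negative skin depended on scaling. TMM factors moved the log2 ratio of CPM by 0.22 towards whole skin, which the pseudocount made less for low genes, and gave 1189 genes higher there and 191 higher in CD326-negative skin (86.2% of calls in whole skin, against 57.9%). The authors' doublet call gave 880 and 216 (80.3%), and cells weighted equally 809 and 327 (71.2%). Pseudocounts of 0.1 and 10 gave 1440 and 1595 (47.4%) and 394 and 201 (66.2%).

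Genes of the epidermal barrier were higher in whole skin as groups. Of the 25 genes of the acylceramide and barrier lipid list, which make and transport the ceramides of the cornified layer, 15 were called higher in whole skin and none in CD326-negative skin, with a median log2 difference of 2.03 and a percentile of 100 among random lists. Acer1, a ceramidase, stood at 68.9 and 4.63 CPM (log2 3.63), Elovl4, which elongates very long fatty acids, at 142 and 11.0 CPM (3.58), the lipoxygenase Alox12b at 12.2 and 0.124 CPM (3.56) and Sptlc3, of serine palmitoyltransferase, at 17.9 and 0.859 CPM (3.35). The 10 members not called included Ugcg (-0.71) and Sptlc2 (-0.55). Of 18 epithelial adhesion genes 16 were called higher in whole skin (median 3.08, percentile 100), among them Cldn4, a claudin (21.1 and 0.692 CPM), the desmosomal Perp (1378 and 113 CPM) and Dsc3 (282 and 23.8 CPM).

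Of 26 measured cornified envelope genes, whose products form the insoluble outer shell of keratinocytes, 20 were called higher in whole skin (median 3.15, percentile 100), as Spink5, a protease inhibitor (95.1 and 3.32 CPM), and Sprr2a3 (107 and 4.42 CPM) show beside Sprr1a and Sprr1b. The list held 5 genes called higher in CD326-negative skin, the late envelope genes Lce1a1, Lce1a2, Lce1b, Lce1c and Lce1m (-2.16 to -3.63). A single cell held 98.9% to 99.4% of the counts of each of these in CD326-negative skin, and without the highest cell of each gene none was called. Lor, which encodes loricrin, the most abundant envelope protein, was the member not called (0.33); 1 cell held 98.6% of its counts in CD326-negative skin, and without the highest cell in each library its difference was 4.09. Members of the Sprr2a and Lce1 families are near-identical copies and share reads, so values of single members are uncertain.

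Genes of connective tissue and mast cells were higher in CD326-negative skin. The 27 fibrillar collagen and matrix genes had a median of -1.15 (percentile 0), and 24 were called higher there. Sparc, a matrix glycoprotein, stood at 4973 and 12512 CPM, tenascin C (Tnc) at 246 and 616 CPM, Col3a1 at 3332 and 8104 CPM and Col5a1 at 132 and 315 CPM. The list of TGF-beta response and myofibroblast genes had a median of -0.88 (percentile 0), with 6 of 19 called. Among them were Il6 (419 and 1008 CPM), Ltbp2 (41.1 and 95.003 CPM), Cthrc1 (43.4 and 99.8 CPM) and Tagln. The mast cell maturation and granule list had a median of -0.98 (percentile 0), with 7 of 18 called. Among these were the mast cell transcription factor Gata2 (60.1 and 147 CPM), Hdc, which makes histamine (138 and 329 CPM), the receptor Kit (43.4 and 101 CPM) and the tryptase Tpsb2 (222 and 491 CPM). Of 12 complement genes 7 were called higher in CD326-negative skin (median -1.03, percentile 0): C1ra (102 and 246 CPM), C3 (266 and 626 CPM), Serping1 (432 and 1013 CPM), Cfb (76.8 and 174 CPM), C1s1, C2 and C4b. The macrophage genes C1qa, C1qb and C1qc of that list stood the other way, at 0.44, 0.51 and 0.62, below the size rule.

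Most of these calls lie near the size rule and do not outlast another scaling, while the medians of these 4 lists stayed below 0. With TMM factors 7 matrix, 2 TGF-beta, 2 mast cell and 3 complement genes were called higher in CD326-negative skin, and with the authors' doublet call 2, 3, 0 and 0. The medians were -0.93, -0.67, -0.76 and -0.82 by TMM and -0.88, -0.71, -0.64 and -0.80 by the authors' call.

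Among inflammatory genes, 10 of 23 cytokine and chemokine genes were called higher in CD326-negative skin (median -0.79, percentile 0). Beside Il6 these included Cxcl1, a chemokine for neutrophils (476 and 1065 CPM), the eotaxin Ccl11 (58.4 and 133 CPM) and Ccl22, a chemokine for T cells (7.60 and 19.98 CPM). Ccl22 was higher there in 8 of 12 hashtags, and 1 cell held 46.7% of its counts in whole skin. With TMM factors 2 genes of the list were called in each direction, Il6 and Ccl22 higher in CD326-negative skin and Ccl8 and Ccl17 higher in whole skin, and with the authors' doublet call 3 (Il6, Cxcl5 and Ccl11) and the same 2. Of 16 type I interferon response genes only Mx2 was called (4.29 and 9.67 CPM, -1.01; not called with TMM factors), with a list median of -0.62 (percentile 0). Cxcl10 stood at 75.5 and 151.7 CPM (-0.998), Ifit1 at -0.84 and Mx1 at -0.75. The removal of keratinocyte-like cells by construction shifts the cytokine and interferon lists, and also the matrix, TGF-beta, mast cell and complement lists. The percentiles of these lists therefore do not show higher levels within cells. Within classes the interferon medians ranged from -0.45 in dendritic cell-like to 0.41 in neutrophil-like cells. None of 9 genes of antigen presentation by MHC class II was called (median -0.34, percentile 12.2). Cd74, the invariant chain, stood at 2235 and 2985 CPM (-0.42), H2-DMb1 at -0.44, H2-DMa at -0.43 and H2-Aa at -0.41.

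The lipid mediator list, which holds genes for prostaglandins, leukotrienes, lysophosphatidic acid and mast cell growth signals, showed no common direction (median -0.09, percentile 56.4; 0.12 with TMM factors). Ptgs1, the constitutive cyclooxygenase (60.2 and 23.1 CPM, 1.35), and Ltc4s, the leukotriene C4 synthase (7.16 and 2.37 CPM, 1.28), were called higher in whole skin. The IL-33 receptor Il1rl1 (77.5 and 166 CPM, -1.09), the prostaglandin E receptor Ptger3 (4.85 and 12.1 CPM, -1.17), Lpar1 and Ptgfr were called higher in CD326-negative skin. These 4 were not called with TMM factors or the authors' doublet call, and Ptgs1 not with the authors' doublet call.

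Cell cycle genes were higher in whole skin (median 0.87, percentile 100), with 5 of 15 called (8 with TMM factors): Ccnb1 (10.0 and 3.04 CPM), Ube2c (28.6 and 11.3 CPM), the topoisomerase Top2a (49.6 and 21.3 CPM), the kinase Cdk1 (17.97 and 7.85 CPM) and Cenpf. All 4 haemoglobin genes were higher in whole skin (median 3.51, percentile 100). Hbb-bs stood at 222 and 18.2 CPM, Hba-a2 at 160.1 and 12.7 CPM, Hba-a1 at 152 and 12.7 CPM and Hbb-bt at 59.2 and 4.98 CPM. The alpha and the beta genes are near-identical pairs, so their single values are uncertain. None of 16 dissociation stress genes was called (median -0.19, percentile 24.3; 0.03 with TMM factors). Hspa1b stood at 37.5 and 18.3 CPM (0.99; called with TMM factors), Atf3 at 1568 and 975 CPM (0.69), Ier3 at -0.54 and Fosb at -0.42. In all, 11 of the 14 lists had a median outside the central 95% of random lists.

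The title of the study names acylceramide of the epidermis and a lipid circuit between mast cells and fibroblasts. Levels by class show in which of the ranked classes, those of 100 or more cells, the transcripts of each were highest. In whole skin 18 of 25 acylceramide and barrier lipid genes were highest in suprabasal keratinocyte-like (13) or sebocyte-like cells (5). Suprabasal keratinocyte-like cells led for Elovl4 (626 CPM), Elovl1 (161 CPM), Abhd5 (135 CPM), the lipid transporter Abca12 (78.1 CPM), Sptlc3 (64.8 CPM), Alox12b (59.5 CPM) and Abhd12b (56.2 CPM). They also led for the ceramide synthase Cers3 (47.5 CPM), Cyp4f39, which hydroxylates very long fatty acids (44.7 CPM), the transglutaminase Tgm1 (38.6 CPM), the acylceramide-forming transacylase Pnpla1 (35.5 CPM), Aloxe3 (25.3 CPM) and Sdr9c7 (21.8 CPM). Sebocyte-like cells led for Cers4 (2759 CPM), the fatty acid transporter Slc27a4 (1063 CPM), Acer1 (485 CPM), Dgat2, which makes triglycerides (137 CPM), and Sptlc1 (46.7 CPM, with an interval that overlapped that of suprabasal keratinocyte-like cells). The other 7 genes had their highest level elsewhere, as Degs1 did in chondrocyte-like cells (171 CPM), most of them with an interval that overlapped that of another class. In CD326-negative skin, where no sebocyte-like cells were left to rank, 13 of the 25 genes were highest in suprabasal keratinocyte-like cells (Elovl1 with an interval that overlapped that of mast cell-like cells). At clustering resolution 0.5 these were 74 cells, under the minimum of 100 for ranking, and 6 genes were highest in basal keratinocyte-like cells.

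Of 25 lipid mediator genes 5 were highest in mast cell-like or fibroblast-like cells in whole skin, and 5 in CD326-negative skin. Mast cell-like cells led for Il1rl1 (821 and 799 CPM), the haematopoietic prostaglandin D synthase Hpgds (199 and 232 CPM) and Ptger3 (33.9 and 32.0 CPM), and fibroblast-like cells for Enpp2, the autotaxin that makes lysophosphatidic acid (553 and 544 CPM). The prostaglandin F receptor Ptgfr was highest in fibroblast-like cells of whole skin (38.4 CPM). Other classes led for other genes: macrophage or monocyte-like cells for Alox5ap (737 and 865 CPM), neutrophil-like cells for the inducible cyclooxygenase Ptgs2 (765 and 769 CPM), and vascular endothelial-like cells for Kitl, the growth factor of mast cells (408 and 416 CPM). Basal keratinocyte-like cells led for Il33, an alarm cytokine (226 and 225 CPM), Schwann-like cells for the lysophosphatidic acid receptor Lpar1 (299.9 and 296 CPM) and chondrocyte-like cells for the prostacyclin synthase Ptgis (207 and 222 CPM). Ptgds was highest in neutrophil-like cells of whole skin (35.1 CPM, from 98 counts) and mast cell-like cells of CD326-negative skin (7.42 CPM). Pla2g3 and Ptgdr reached only 0.767 and 1.93 CPM in their highest class of whole skin. Melanocyte-like and Langerhans cell-like cells were too few to rank. The top 10 genes of the former held Ptgds, and those of the latter Ltc4s, Ptgs1 and Alox5. With the authors' doublet call 3 of the 25 were highest in mast cell-like or fibroblast-like cells in CD326-negative skin.

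**Figure D2:**
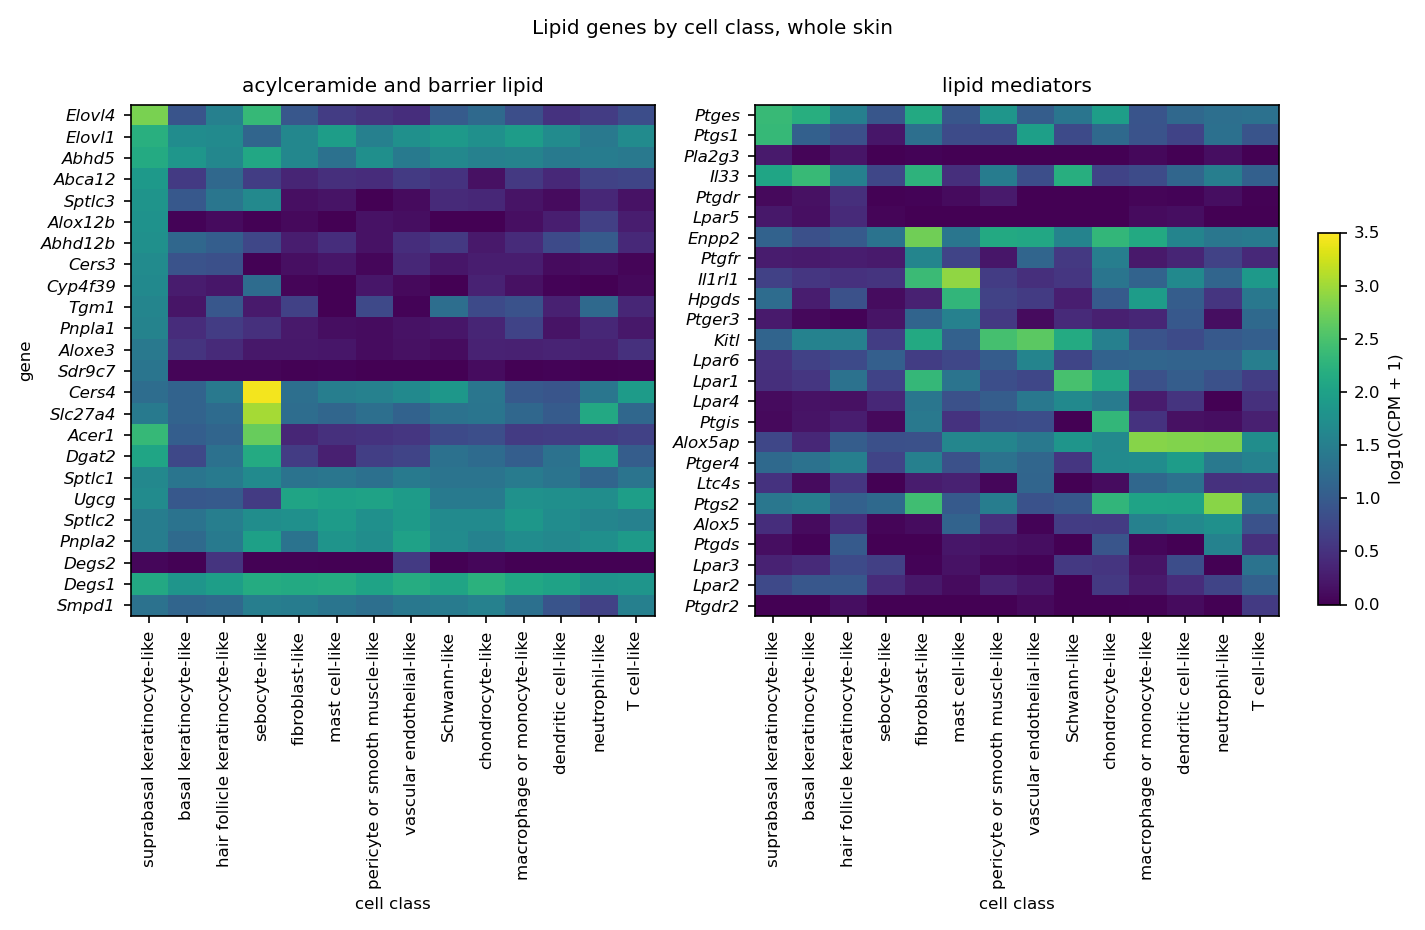
Level of 24 acylceramide and barrier lipid genes (left) and the 25 lipid mediator genes (right) in the classes of 100 or more cells of whole skin, as log10(CPM + 1) in colour, genes in order of their highest class. Suprabasal keratinocyte-like and sebocyte-like cells hold the highest level of 18 of the 24 genes on the left, up to 2759 CPM for Cers4 in sebocyte-like cells, while the highest levels on the right are spread over many classes.

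Within a class, the largest differences between the 2 preparations included transcripts that are typical of other classes. In T, dendritic, mast and vascular endothelial-like cells the largest differences towards whole skin included those of keratinocyte genes. Krt14, a keratin of the basal layer, was 1005 and 104 CPM in T cell-like cells (log2 3.26), 993 and 13.2 CPM in dendritic cell-like cells (6.13) and 664 and 27.8 CPM in vascular endothelial-like cells (4.53). Its partner Krt5 was 197 and 7.03 CPM in mast cell-like cells (4.62). In each of the 7 classes other than basal keratinocyte-like cells, Krt14, Krt5 and Krt15 were called higher in whole skin. Haemoglobin led in fibroblast-like cells (Hbb-bs, 283 and 2.94 CPM), basal keratinocyte-like cells (Hba-a2, 153 and 0.636 CPM), macrophage or monocyte-like cells (Hbb-bt, 59.6 and 4.88 CPM) and neutrophil-like cells (Hbb-bs, 4703 and 7.22 CPM). Single cells held 48.6%, 46.9%, 61.5% and 90.6% of these counts in whole skin. In the other direction the collagen genes Col3a1 (89.2 and 502 CPM), Col1a2 and Col1a1 were higher in vascular endothelial-like cells of CD326-negative skin. The endothelial genes Fabp4 (5.43 and 59.2 CPM) and Selp (9.11 and 62.4 CPM) were higher in its mast cell-like cells, and the matrix genes Tnn (1.86 and 66.4 CPM) and Col6a2 (15.8 and 269.9 CPM) in its basal keratinocyte-like cells. Of 12 hashtags, Tnn was higher there in 2 and lower in 2, and Col6a2 higher in 9 and lower in 3. A single cell held 53.6% of the Tnn counts there.

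The cytokine and chemokine list had no common direction within classes, with medians from -0.54 in basal keratinocyte-like to 0.12 in macrophage or monocyte-like cells. In the latter 2 of its genes were called higher in whole skin and 3 in CD326-negative skin, and in fibroblast-like cells 0 and 0. Some single genes were higher in CD326-negative skin. In mast cell-like cells Ptgfrn (29.4 and 81.9 CPM) and Il1b (20.2 and 55.2 CPM) were higher in CD326-negative skin, in 11 and 10 of 12 hashtags. Macrophage or monocyte-like cells were a cluster led by Arg1 and Chil3, with 677 and 931 cells, and a cluster led by Ccl8 and C1qc, with 407 and 233, so their mix differed between the preparations. They had more of Mmp13, a collagenase (13.3 and 56.0 CPM, 8 hashtags), haptoglobin (Hp, 45.5 and 109 CPM, 10 hashtags) and Cxcl10 (33.4 and 79.6 CPM, 10 hashtags) in CD326-negative skin. T cell-like cells had more of Ly6c1 (29.2 and 94.8 CPM, 11 hashtags) and Il6 (25.8 and 81.0 CPM, 10 hashtags, with 40.8% of counts in 1 cell). In fibroblast-like cells 3 annotated genes of 50 CPM or more were higher in CD326-negative skin: Angptl7 (33.7 and 94.95 CPM, 9 hashtags), Cxcl9 (52.8 and 140.0 CPM, 7 hashtags) and Grip2, a scaffold protein (283 and 680 CPM, 12 hashtags). The difference of Grip2 was not particular to fibroblast-like cells, since it was called in all 8 classes, at log2 -1.42 to -1.21. The collagen and matrix list had a median of -0.01 within fibroblast-like cells and the mast cell list 0.02 within mast cell-like cells, against -1.15 and -0.98 over all cells. In other classes the matrix list was lower in whole skin, with medians of -2.16 in basal keratinocyte-like, -1.25 in neutrophil-like, -0.85 in T cell-like, -0.82 in dendritic cell-like, -0.74 in macrophage or monocyte-like and -0.70 in vascular endothelial-like cells, but 0.17 in mast cell-like cells. The mast cell list had medians above 0 in dendritic cell-like (1.28), macrophage or monocyte-like (0.91) and neutrophil-like cells (0.51), and of -0.34 to -0.06 in the other 4 classes. Its summed level was higher in whole skin in dendritic cell-like cells (3142 and 2773 CPM). The sum was lower in whole skin in macrophage or monocyte-like (2938 and 4079 CPM) and neutrophil-like cells (19353 and 21758 CPM). Within fibroblast-like cells the TGF-beta and complement lists had medians of -0.04 and 0.01, with none of their genes called. Over the 8 classes these medians ranged from -0.33 to -0.0036 and from -0.87 to 0.37. By the size rule 84 genes were higher in whole skin and 42 in CD326-negative skin among fibroblast-like cells, 305 and 294 among T cell-like and 259 and 86 among macrophage or monocyte-like cells. There were 240 and 326 among mast cell-like, 415 and 360 among dendritic cell-like, 392 and 441 among neutrophil-like, 260 and 300 among vascular endothelial-like and 468 and 552 among basal keratinocyte-like cells. Whole skin held more of them under every setting run in fibroblast-like and macrophage or monocyte-like cells, but in the other 6 classes the direction with more genes changed with the setting. In basal keratinocyte-like cells there were 897 and 275 with the highest cell of each gene left out, 622 and 446 with TMM factors, 295 and 782 with barcodes of several hashtags kept, and 262 and 54 when 10 of 12 hashtags had to go in the same direction. Counts of called genes within classes were set largely by low genes: a pseudocount of 10 left 26 in fibroblast-like and 74 in T cell-like cells.

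Hashtags marked 58.3% of whole skin barcodes (57.5 to 59.1) and 48.9% of CD326-negative barcodes (48.2 to 49.7) with 1 hashtag under the 75% rule, 8998 and 8264 barcodes, and each of these carried the same hashtag in the authors' call. Several hashtags were left for 6440 and 8630 barcodes, and 0 and 1 barcodes had under 10 hashtag counts; the authors had called 498 (3.23%) and 595 (3.52%) barcodes doublets. Over the 12 hashtags, whose conditions are not given in the sources used here, the share of keratinocyte-like cells ranged from 12.3% to 71.4% (median 40.1%) in whole skin and from 0.748% to 14.7% (median 4.16%) in CD326-negative skin. Fibroblast-like cells ranged from 7.39% to 17.4% (median 11.9%) and from 19.9% to 34.5% (median 22.7%), and mast cell-like cells from 2.14% to 6.16% (median 4.12%) and from 4.50% to 15.05% (median 9.14%).

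**Figure D3:**
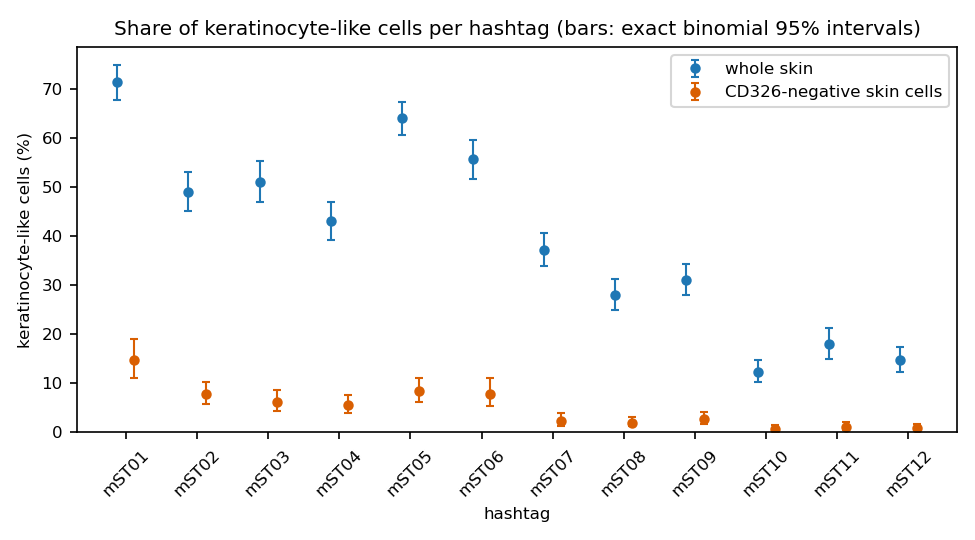
Share of keratinocyte-like cells (%) among the cells of each of the 12 hashtags in whole skin (blue) and CD326-negative skin (orange), with exact binomial 95% intervals as bars. The share in CD326-negative skin is below that in whole skin for each hashtag, and hashtags range from 12.3% to 71.4% in whole skin.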

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

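The authors' doublet call, alone or with cells clustered afresh, the requirement that 10 of the 12 hashtags go in the same direction, and the removal of the highest cell of each gene were chosen only after the results were seen; the other alternatives were set beforehand. Of the key results, 110 values under alternatives other than leaving out a hashtag stayed within their interval or within 1.5 times of their count, and 56 moved; of the single genes, lists and classes, 519 stayed, 170 moved and 4 reversed. The 4 are Lce1a1 (0.14), Lce1a2 (0.0207), Lce1b (0.17) and Lce1m (0.65), called higher in CD326-negative skin, which turned sign when the cell with the highest count of each gene was left out, since 1 cell held nearly all their counts there. The medians of the lipid mediator and dissociation stress lists, near 0, changed sign with TMM factors. The macrophage or monocyte-like share, given with the class shares, had overlapping intervals under the authors' doublet call, as did the dendritic cell-like share. No paired analysis was run. Each preparation is 1 library, the results come from no test, and no source used here says that a hashtag name marks the same animals in both. Equally named hashtags were compared only as a description. The limit of 200 detected genes and the omission of the minimum count removed nothing and so say nothing about stability. Counting error set the precision of shares of rare classes, and differences of genes under a few CPM are understated by the pseudocount.

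Fibroblast-like cells of whole skin were 17.5% with barcodes of several hashtags kept, 17.4% by the authors' doublet call and 10.6% by that call clustered afresh, where a cluster of 653 whole skin and 1387 CD326-negative cells led by Cxcl5, Timp1 and Ptx3, with a mean log2 excess of fibroblast markers of 2.29, stayed unnamed, 11.2% and 11.0% at clustering resolutions 0.5 and 2, and 13.2% with each library clustered alone. In CD326-negative skin they were 31.4% with several hashtags kept, 31.4% by the authors' call, 18.7% clustered afresh, and 23.2% and 22.8% at resolutions 0.5 and 2. Keratinocyte-like cells of whole skin were 39.6% without a mitochondrial limit, 35.7% with several hashtags kept, 34.7% at resolution 2, 33.5% clustered alone, 35.9% by the authors' call and 36.5% afresh. In CD326-negative skin they were 4.76% without that limit, 3.10% with several hashtags kept, 3.14% by the authors' call and 3.21% afresh. Under a 90% hashtag limit 5505 CD326-negative barcodes were assigned, and the median fibroblast-like share over hashtags was 6.66% in whole skin and 10.7% in CD326-negative skin.

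Genes higher in whole skin numbered 1440 with a pseudocount of 0.1 and 394 with 10. Genes higher in CD326-negative skin numbered 1595 and 201 with these, 327 with cells weighted equally, 191 with TMM factors, 207 with several hashtags kept and 216 by the authors' doublet call. The log2 difference of Epcam was 3.33 with cells weighted equally and 3.29 in thinned counts, and that of Abhd12b 2.40 and 2.55. Of the acylceramide and barrier lipid genes 6 were highest in keratinocyte-like cells of CD326-negative skin at resolution 0.5, all in basal ones, because only 74 suprabasal cells were left there, too few to be ranked. Of the lipid mediator genes 3 were highest in mast cell-like or fibroblast-like cells there by the authors' call. Apart from that ranking and the pseudocounts and stricter limits, which by construction let more or fewer genes or barcodes pass, the cause was not tested.

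Within classes, genes at least 2-fold apart in either direction numbered 599 in T cell-like, 1020 in basal keratinocyte-like, 775 in dendritic cell-like, 126 in fibroblast-like, 345 in macrophage or monocyte-like, 566 in mast cell-like, 833 in neutrophil-like and 560 in vascular endothelial-like cells. With a pseudocount of 10 they numbered, in that order, 74, 171, 116, 26, 60, 61, 304 and 89. With each library clustered alone there were 906 in T cell-like, 270 in fibroblast-like and 626 in macrophage or monocyte-like cells; the cause was not tested. The direction with more genes changed with the setting in all of these classes but fibroblast-like and macrophage or monocyte-like cells. Requiring 10 of 12 hashtags left 218 in T cell-like, 316 in basal keratinocyte-like, 188 in dendritic cell-like, 174 in macrophage or monocyte-like, 153 in mast cell-like and 148 in vascular endothelial-like cells, and 0 in neutrophil-like cells, for which only 7 hashtags had counts in both libraries.

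Leaving out each hashtag in turn gave log2 differences of 2.68 to 2.80 for Abhd12b and 3.54 to 3.69 for Epcam, 917 to 992 genes higher in whole skin and 540 to 902 in CD326-negative skin. Fibroblast-like cells were then 11.5% to 12.3% of whole skin and 23.6% to 25.1% of CD326-negative skin, and keratinocyte-like cells 35.8% to 41.5% and 3.46% to 4.40%.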

Other observations

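Among the tests weighed here, those of low Epcam in remaining basal keratinocytes and in the cell that held the Lce1 counts, and that of free keratin RNA, were chosen only after the result was seen. Several clusters inside the named classes carried gene programmes that the comparisons do not describe. T cell-like cells held a cluster led by Il17a, Il23r, Blk and Cd163l1, genes of interleukin-17-producing gamma delta T cells, with 255 cells of whole skin and 433 of CD326-negative skin. They also held a cluster with Foxp3, Ctla4 and Tnfrsf4, genes of regulatory T cells, among its top 10 genes, with 311 and 455. Its top 10 also held Cd28, Trac, Cd5, Cd6 and Cd2, so these numbers do not count regulatory T cells. Macrophage or monocyte-like cells held a cluster led by Arg1, Chil3 and Ccl24, genes of alternative activation, with 677 and 931 cells, and a cluster led by Cd163, Pf4, C1qc and Ccl8, genes of resident macrophages, with 407 and 233. An unnamed cluster led by Alox15, Prg2, Ccr3 and F5, of which Prg2 and Ccr3 are known from eosinophils, held 100 cells of whole skin and 23 of CD326-negative skin.

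The 12 hashtags have no condition in the sources used here, and their values are given without one. In whole skin keratinocyte-like cells made up 71.4%, 49.1%, 51.1%, 43.1%, 64.1%, 55.7%, 37.2%, 28.0%, 31.2%, 12.3%, 17.98% and 14.7% of the cells of mST01 to mST12 in order, without a clear gap. Neutrophil-like cells made up 0%, 0%, 0%, 0.153%, 0% and 0% of mST01 to mST06 and 3.55%, 6.14%, 3.89%, 3.99%, 6.05% and 12.03% of mST07 to mST12, so these values fell into 2 clusters. Macrophage or monocyte-like cells also fell into 2 clusters, with 3.30%, 3.56%, 4.94%, 4.43%, 3.46% and 4.46% of mST01 to mST06 and 19.7%, 20.2%, 20.0%, 20.5%, 14.3% and 21.1% of mST07 to mST12. In CD326-negative skin the same classes made up 0%, 0%, 0.374%, 0.147%, 0.185%, 0%, 9.25%, 8.19%, 6.60%, 5.80%, 8.40% and 8.68% (neutrophil-like) and 6.58%, 2.83%, 3.36%, 2.21%, 3.70%, 5.18%, 20.4%, 24.7%, 19.7%, 18.2%, 17.4% and 25.2% (macrophage or monocyte-like) of mST01 to mST12. Abhd12b in keratinocyte-like cells of whole skin was 49.7, 53.5, 37.0, 17.7, 19.0, 24.9, 53.6, 34.3, 35.1, 11.9, 9.48 and 18.7 CPM in mST01 to mST12. It was thus 34.3 CPM or more in mST01 to mST03 and mST07 to mST09, and 24.9 CPM or less in the others. In CD326-negative skin the same hashtags held 29.2 to 62.1 CPM and the others 3.40 to 20.6 CPM, from 2 to 138 counts per hashtag.

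The Lce1 genes were higher in CD326-negative skin while most cornified envelope genes were lower there. Of the 46061 counts of the 14 Lce1 family genes, 99.3% lay in hashtag mST01 and 99.8% in the top 1% of cells, against free RNA, which would spread over cells; 1 suprabasal keratinocyte-like cell with 199048 counts held 45712 of them. Reads split between near-identical copies would cancel in a sum, but all 18 Lce genes together stood at 9.34 and 121 CPM, a log2 difference of -3.56. Late keratinocytes that escape the depletion through low Epcam would have been excluded by the bound of 100% set before the result was seen, since in whole skin the 8 keratinocyte-like cells with 20 or more Lce1 counts held 294% (266 to 323) of the Epcam level of the others, but that bound was wrong in not covering the cell that carries the pattern, which had 37.7% (21.1 to 62.3) of that level from 15 counts, so this stays open. In these libraries the higher Lce1 level of CD326-negative skin thus rested on 1 cell. Without it the family stood at 7.18 and 0.901 CPM (log2 2.10), higher in whole skin. No biological explanation was tested.

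Basal keratinocyte-like cells left in CD326-negative skin carried more collagen and matrix RNA than those of whole skin, 7477 against 1549 CPM over the list. The medians over single cells were closer, 1352 against 980 CPM, so a minority of cells held much of the difference. In CD326-negative skin the 20% of these cells with the most matrix counts held 88.3% of them, against 63.2% in whole skin. Doublets with fibroblasts would raise the total of a cell. The 42 cells with the highest matrix share of their counts, a different ranking, had a median total 0.7997 times (0.578 to 1.07) that of the others. Since a share has the total as its denominator, that ranking favours cells with low totals. The test therefore cannot decide, and doublets stay open, those of small cells among them. Free RNA stays open: the median matrix gene stood at 3.12 times (1.57 to 3.87) its counts per cell in T, mast and neutrophil-like cells, with genes from 0.894 to 10.1 times. Whether cells low in Epcam that pass the depletion are part of the matrix difference cannot be told. Without the 20% of cells highest in matrix share, the remaining cells held 0.555 times (0.491 to 0.626) the Epcam level of basal keratinocyte-like cells in whole skin. Any depletion by CD326 would leave cells low in Epcam. The ratio also leaves out the cells highest in matrix share, so it does not link low Epcam to matrix RNA. No biological explanation was tested.

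Keratin RNA was higher in the other classes of whole skin than in those of CD326-negative skin. Free RNA as its whole cause would give each class a like number of counts per cell, but 5 keratin genes together ranged from 17.2 counts per cell in mast cell-like to 98.4 in dendritic cell-like cells, 5.71 times apart. Doublets with keratinocytes cannot be told apart from other causes, since in the median class 1% of the cells held 43.9% of the keratin counts. A low even layer of free RNA stays open beside them, as the median cell of each of the 7 classes held 3 to 9 keratin counts in whole skin and 0 to 1 in CD326-negative skin. No biological explanation was tested.

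The same 12 hashtag names occur in both libraries, and a hypothesis is that a name marks the same animals in both. Levels in fibroblast-like cells alone were used, without haemoglobin and keratin genes, centred per gene over the hashtags of a library. Over 10851 genes, 6 of the 12 hashtags of whole skin correlated best with the equally named hashtag in CD326-negative skin. Chance would give 1, and from the other side 4 did. Correlations of equal names, taken across genes, which are not independent replicates, ranged from 0.246 to 0.724 (median 0.366), and the highest of unequal names was 0.569. The names may thus mark the same animals, but a structure shared by several hashtags would also raise the number of matches.

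Grip2, Plin1 and Sertm1, chosen after their values were seen, were higher in CD326-negative skin. Within a library their levels differed up to 1.83 times between classes of 100 or more cells. Grip2 and Plin1 were called in all 8 classes compared, as were the unannotated Gm15039, Gm15042, Gm15045, Gm48159 and Gm7295, and Sertm1 in 7. These differences were thus not those of 1 class, and their cause was not tested. Grip2 ranged from 269 to 341 CPM over 14 classes of whole skin and from 664 to 912 CPM over 12 classes of CD326-negative skin, Plin1 from 11.2 to 19.6 and from 30.4 to 44.5 CPM, and Sertm1 from 6.09 to 11.1 and from 18.5 to 27.8 CPM.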
